A study of Mus musculus with 12 samples.

How the data were processed

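RNA abundance was measured by paired-end sequencing in 12 libraries of the mouse cell line GC-2, 3 in each of 4 groups. The sample titles name GC-2 throughout, but the cell type label counts up from GC-2 to GC-13 over the samples, and all samples were taken as GC-2 without a test of identity. The groups cross treatment (DMSO, the solvent control, or MLN4924 at 1 µM) with oxygen (normoxia, or hypoxia at 1% O2) over 24 h. The series text calls the 3 libraries of a group biological replicates. Per the labels, total RNA was extracted with RNAiso Plus, purified on RNeasy columns, made into libraries with the NEBNext Ultra RNA kit and sequenced on the NovaSeq platform with reads of 150 nt. The submitters' processing notes name fastp, STAR and RSEM 1.3.3 with genome build mm39, without giving the role or order of each tool. The gene annotation, the strandedness of the libraries and any filter were not stated.

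The values used were FPKM (fragments scaled by transcript length and by mapped fragments), computed by the authors and rounded to 2 decimals, with 1 column per library and 24770 gene symbols. No symbol occurred more than once, no pair of columns was identical, and every column of values was used. Column totals differed, from 530452 to 633597 FPKM, so the values were not TPM. FPKM carries no read counts, so the sequencing depth of each library was unknown and no counting interval could be given. Relative depth was estimated from 175 low genes whose non-zero values were nearly constant (a ratio under 1.35), as single fragments would give, and it ranged from 0.952 to 1.03 between libraries. Because genes were chosen for being alike across libraries, this range was limited in advance and cannot show that depths were alike. The total FPKM of a library and the scatter between its replicates were used in place of depth. Genes were identified by symbol, as in the file. The annotation at hand was GENCODE for the preceding genome build, so no chromosome positions are given, and it was used only for transcript length and GC content by symbol. Of the symbols, 96.0% were found there, and 97.5% of the tested genes had a transcript length.

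Genes with at least 1 FPKM in at least 3 of the 12 libraries were tested, 12311 in all. Values were transformed as log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group, a spread shared across the 4 groups and an intensity trend in the prior variance. The 5 contrasts were hypoxia against normoxia in DMSO, MLN4924 against DMSO in normoxia, MLN4924 against DMSO in hypoxia, hypoxia against normoxia in MLN4924, and the interaction (the hypoxia effect with MLN4924 minus that with DMSO). P-values were two-sided and adjusted by the Benjamini-Hochberg method over the tested genes within a contrast, with 0.05 as the threshold. A gene is said to rise or fall where it passed that threshold. Fold changes are on the scale of FPKM + 1, which understates the change of genes near or below 1 FPKM. Where all libraries of a group were listed at 0, no fold is given. An exact permutation test of 3 libraries against 3 cannot give a p below 0.1, so the moderated limma test was used. The count model of other tools was not applied because FPKM are not counts.

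For groups of genes, 29 lists with 810 members were fixed, of which 765 members were in the file. They were glycolysis; HIF targets outside glycolysis; p53 targets; apoptosis regulators that promote or that oppose death; NRF2 targets; the integrated stress response; endoplasmic reticulum chaperones and the unfolded protein response; heat shock and proteotoxic stress; G1/S and DNA replication; G2/M and mitosis; DNA damage repair; neddylation machinery and cullin-RING ligase parts; proteasome subunits; NF-kB and inflammatory genes; interferon-stimulated genes; cholesterol biosynthesis; the nuclear-encoded respiratory chain; mitochondrially encoded transcripts; cytosolic ribosomal proteins; autophagy and lysosome; YAP/SRF and cytoskeleton targets; extracellular matrix; and markers of spermatogonia, spermatocytes and spermatids, Sertoli cells, Leydig cells, fibroblasts and peritubular cells, and macrophages and leukocytes. The 26 lists with at least 3 tested members were compared with all other tested genes by camera in limma, with a preset correlation of 0.01 between members. P-values were adjusted over all lists and contrasts. Each list was tested again with the correlation estimated from the data, and with fry, which asks whether the members of a list move 1 way on balance. For each list, the number of members past 0.05 is given with adjustment over all tested genes and with adjustment over the list alone.

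The lists, the contrasts, the filter, the tests and the rule for named genes were chosen before the data were examined. For each contrast the rule took the 6 genes with the largest positive and the 6 with the largest negative log2 fold change among those with an adjusted p under 0.05, a mean of at least 5 FPKM in the higher group, no overlap between the libraries compared (not required for the interaction), and a symbol that is not a predicted or clone name. It further took up to 3 members of each list with the largest change past the threshold, or the member with the smallest p where none passed. It added these anchor genes in every contrast: Cdkn1a, Cdt1, Hif1a, Vegfa, Bnip3, Nqo1, Hmox1, Bbc3, Ddit3, Trp53, Mdm2, Nedd8, Nae1 and Uba3. By chance, 10% of genes show no overlap between 3 libraries and 3 others.

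The alternatives tried were a pseudocount of 0.1 FPKM, no filter, a mean of at least 5 FPKM, values rescaled to equal totals, median-of-ratios scaling, quantile normalization, a replicate block, array weights, a fit of only the groups compared, and each library left out in turn. A further alternative, which removed each library's trend with transcript length, and the fits without DMSO hypoxia replicate 1 for contrasts that do not hold its group, were chosen after seeing the data. The tests were checked on simulated data, where effects were added to 200 genes over normal noise with the spread of each gene and library. With a log2 fold change of 1, 83.6% of changed genes were recovered for hypoxia in DMSO and 89.6% for MLN4924 in normoxia. With a log2 fold change of 0.5, 55.2% and 53.7% were recovered. Of 12111 unchanged genes, 28 and 2 were called. A shifted gene list was recovered and 0 of 25 other lists were called. Genes were simulated as independent, so this check does not show how often lists with correlated members are called falsely. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. The values of 1 named gene are not reported here.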

Results

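Gene expression was profiled in GC-2 cells, a mouse line that the labels describe as type B spermatogonia, after 24 h with DMSO or with 1 µM MLN4924 under normoxia or hypoxia (1% O2). MLN4924 inhibits the NEDD8-activating enzyme, made of Nae1 and Uba3, and so blocks the attachment of the ubiquitin-like protein NEDD8 to cullins, which the cullin-RING ubiquitin ligases need for activity. The series title concerns whether this inhibition adds to apoptosis caused by hypoxia. There were 12 libraries, 3 in each of the 4 groups. Totals ran from 530452 to 633597 FPKM per library, and 11180 to 11644 genes per library reached 1 FPKM. Group values below are means ± SD of 3 libraries in FPKM, fold changes are on the FPKM + 1 scale, and log2 fold changes carry the standard error (SE) of the limma fit. The median SE over genes was 0.13 for the pairwise contrasts and 0.19 for the interaction. The added 1 FPKM makes fold changes of genes with low values smaller than their ratio of FPKM.

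DMSO hypoxia replicate 1 stood apart from the other libraries. Its total was 633597 FPKM, against 530452 to 557779 in the other libraries. Its mean Spearman correlation across genes with the rest of its group was 0.926, while libraries of the other groups reached at least 0.977 within their own group. Its deviation from its group followed transcript length, with a Spearman rho of -0.478 across genes, and no library of another group exceeded 0.0734 in size. Of 5 bins of genes by transcript length, the shortest lay 0.34 log2 units above the other libraries of the group and the longest lay at -0.39. Its array weight was 0.0736. Each main count is therefore given also without this library. The mitochondrially encoded list took 5.72% to 8.12% of FPKM in the hypoxia libraries and 10.2% to 12.3% in the normoxia libraries.

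**Figure D1:**
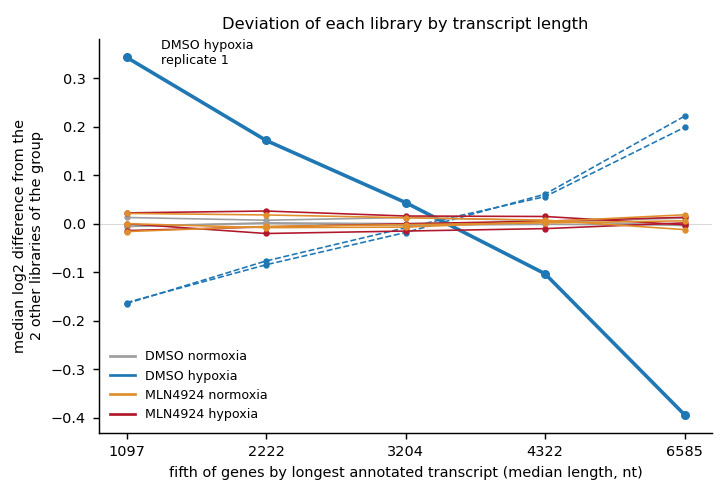
Median log2 difference of each library from the 2 other libraries of its group (vertical axis), in 5 bins of genes ranked on annotated transcript length (horizontal axis, median length of each bin in nt), with 1 line per library coloured by group. DMSO hypoxia replicate 1 runs from 0.34 at the bin with a median of 1097 nt to -0.39 at the bin with a median of 6585 nt.

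The response to hypoxia without the inhibitor was measured by DMSO hypoxia against DMSO normoxia. Adm, which encodes the vasodilator adrenomedullin, rose from 0.783 ± 0.179 to 31.6 ± 4.51 FPKM, a log2 fold change of 4.19 ± 0.13 (adjusted p = 1.72e-08). Ndrg1 rose by 3.70 on the log2 scale, from 47.3 ± 0.892 to 630 ± 66.5, and Ero1a, an oxidase of protein folding in the endoplasmic reticulum, rose 12.3-fold, from 16.9 ± 1.20 to 220 ± 26.3. Cdkn1a, the cyclin-dependent kinase inhibitor p21, rose 9.04-fold, from 16.9 ± 1.21 to 161 ± 8.45 (adjusted p = 1.18e-09). The HIF target Ankrd37 rose 9.19-fold and the keratin Krt19 rose 8.92-fold. The interferon-induced genes Ifit3 and Ifit1 fell, from 91.6 ± 12.7 to 6.98 ± 0.571 FPKM (log2 fold change -3.53 ± 0.12) and from 83.4 ± 6.55 to 11.3 ± 1.303 (-2.79 ± 0.08). Ifit3b fell by 3.38 on the log2 scale, but reads of Ifit3 and Ifit3b are hard to assign to 1 of these close paralogs. Pcbd2 also ranked among the largest falls, but its call rested on a large error (-3.98 ± 1.31, adjusted p = 0.0396) and ended without DMSO hypoxia replicate 1 (adjusted p = 0.0666) and with each other library of either group left out in turn. The fall of Uba7, the activating enzyme of ISG15, was -3.09 ± 0.50 and became -2.42 without DMSO hypoxia replicate 1.

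Of the HIF targets outside glycolysis, 27 of 33 tested rose and 2 fell, the same numbers as when adjusted over the list alone (camera adjusted p = 3.37e-24; adjusted p = 0.00366 with an estimated correlation). Bnip3, a mitophagy receptor with a BH3 domain, rose 4.77-fold, from 172 ± 7.77 to 844 ± 229, and Vegfa, the main angiogenic growth factor, rose 3.72-fold, from 36.5 ± 1.01 to 139 ± 8.76. Hif1a itself fell from 46.3 ± 0.557 to 28.8 ± 2.62 (log2 fold change -0.67 ± 0.06, adjusted p = 3.57e-05). Of 20 glycolysis genes, 17 rose and 0 fell (17 and 1 adjusted over the list alone, camera adjusted p = 5.27e-16; adjusted p = 0.00317 with an estimated correlation). Pfkp, a phosphofructokinase, rose 3.21-fold and Pgk1 rose from 927 ± 37.1 to 2556 ± 424. In the integrated stress response list, 24 of 30 genes rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 1.79e-17; adjusted p = 0.0145 with an estimated correlation). Trib3, a pseudokinase induced by ATF4 and CHOP, rose 5.86-fold, Chac1, which degrades glutathione, rose 3.64-fold, and Ddit3, which encodes CHOP, rose 3.36-fold, from 25.5 ± 0.525 to 88.7 ± 13.5.

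G2/M and mitosis genes rose in 25 of 40 cases and fell in 0 (25 and 1 adjusted over the list alone, camera adjusted p = 6.35e-10; adjusted p = 0.0354 with an estimated correlation and 0.0588 without DMSO hypoxia replicate 1). The spindle genes Kif23 and Tpx2 rose 2.02-fold and 1.73-fold. Of 33 interferon-stimulated genes 26 fell and 1 rose (27 and 1 adjusted over the list alone, camera adjusted p = 1.56e-14; adjusted p = 0.0218 with an estimated correlation and 0.0509 without that library). The chemokine Cxcl10, a member of the NF-kB list and not of this one, fell from 95.3 ± 6.11 to 18.1 ± 3.24. In the heat shock list 13 of 18 genes fell and 0 rose, with the same counts adjusted over the list alone (camera adjusted p = 2.84e-06; adjusted p = 0.0145 with an estimated correlation). The chaperone genes Hspa1b and Hsph1 fell by 1.37 and 1.29 on the log2 scale, with the caution that Hspa1a and Hspa1b are nearly identical. Of 24 cholesterol biosynthesis genes 10 fell and 1 rose (12 and 1 adjusted over the list alone, camera adjusted p = 0.00624; adjusted p = 0.0477 with an estimated correlation).

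Several lists passed with the preset correlation only. Of 32 proteasome subunits 22 fell and 1 rose (23 and 1 adjusted over the list alone, camera adjusted p = 1.23e-07; adjusted p = 0.349 with an estimated correlation, or 0.0299 without DMSO hypoxia replicate 1). Psmd1 fell from 117 ± 3.77 to 56.6 ± 1.92. Of 45 cytosolic ribosomal protein genes 33 rose and 0 fell (36 and 0 adjusted over the list alone, camera adjusted p = 2.54e-11; adjusted p = 0.402 with an estimated correlation). These transcripts are short, and in DMSO hypoxia replicate 1 short transcripts were high. The list mean lay 0.70 above DMSO normoxia in that library and 0.22 and 0.24 above it in replicates 2 and 3, and the list median of 0.39 became 0.21 without it. The rise was smaller but kept its call without that library, where 36 genes rose and 1 fell (camera adjusted p = 9.82e-14, and 0.0643 with an estimated correlation). Rpl3 had a log2 fold change of 0.72 ± 0.10. Of 33 NRF2 targets 18 fell and 5 rose (19 and 6 adjusted over the list alone, camera adjusted p = 0.00547; adjusted p = 0.365 with an estimated correlation, or 0.0195 without that library). Nqo1 fell from 30.5 ± 1.13 to 18.4 ± 2.25, whereas Hmox1, a heme oxygenase, rose 2.54-fold. Of 13 mitochondrially encoded transcripts 7 fell and 0 rose, as when adjusted over the list alone (camera adjusted p = 0.0193; adjusted p = 0.412 with an estimated correlation). This call ended without DMSO hypoxia replicate 2 (0.0548) or DMSO normoxia replicate 1 (0.0574). mt-Nd1 fell from 4337 ± 377 to 2191 ± 133.

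Genes of cell death moved in both directions. Of 28 apoptosis regulators that promote death, 5 rose and 8 fell (5 and 9 adjusted over the list alone, camera adjusted p = 0.889), and of 16 that oppose death 1 rose and 1 fell, also when adjusted over the list alone (0.781). Bbc3, which encodes the BH3-only protein PUMA, rose 2.10-fold, from 1.73 ± 0.443 to 4.73 ± 0.700 FPKM. Bid fell from 8.62 ± 0.945 to 1.40 ± 1.59, with a log2 fold change of -2.23 ± 0.41, and -2.74 without DMSO hypoxia replicate 1. Birc5, which encodes the inhibitor of apoptosis and mitotic protein survivin, rose 1.55-fold. Of 29 p53 targets, 7 rose and 7 fell (7 and 8 adjusted over the list alone, camera adjusted p = 0.484). Trp53 transcripts fell from 2084 ± 31.7 to 1476 ± 114, and Mdm2 had a log2 fold change of 0.12 ± 0.09 (adjusted p = 0.347). GC-2 cells were immortalised with SV40 large T antigen and a p53 mutant, and a value per gene does not separate introduced from endogenous Trp53 transcripts. Of 40 neddylation and cullin-RING genes 2 rose and 9 fell, the same adjusted over the list alone (camera adjusted p = 0.612), with log2 fold changes of -0.11 ± 0.12 for Nedd8 and -0.09 ± 0.11 for Nae1, neither past the threshold. Uba3 rose (log2 fold change 0.48 ± 0.10, adjusted p = 0.00339).

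The remaining lists did not pass for hypoxia in DMSO. Counts of genes that rose and fell were 8 and 3 of 46 for G1/S and DNA replication (camera adjusted p = 0.0832), 7 and 3 of 30 for DNA damage repair (0.230), 4 and 9 of 22 for the endoplasmic reticulum and unfolded protein response list (0.454), 3 and 10 of 24 for NF-kB and inflammatory genes (0.0610), and 1 and 7 of 41 for the nuclear-encoded respiratory chain (0.975). They were 6 and 6 of 29 for autophagy and lysosome (0.876), 6 and 9 of 29 for YAP/SRF targets (0.470), 9 and 8 of 29 for extracellular matrix (0.494), 1 and 1 of 5 for spermatogonial markers (0.484), 1 and 1 of 9 for Sertoli cell markers (0.519), and 2 and 2 of 9 for fibroblast markers (0.757). Too few members were tested for a list test of spermatocyte markers (1 rose of 1), Leydig cell markers (0 rose and 1 fell of 2) and macrophage markers (0 of 2). Median, mean and test differed in sign for the autophagy, extracellular matrix and fibroblast lists. Without DMSO hypoxia replicate 1 the unfolded protein response (0.0289), respiratory chain (0.00283) and extracellular matrix (0.00578) lists passed. With an estimated correlation only the extracellular matrix list then did (0.0461), against 0.264 and 0.211 for the others. The G1/S list did without DMSO hypoxia replicate 2 (0.0457). Without DMSO normoxia replicate 1 or 3 the NF-kB list passed (0.0467 and 0.0456). With all libraries and an estimated correlation the G1/S and NF-kB lists had 0.402 and 0.189. Leaving out DMSO hypoxia replicate 1 moved the falling genes from 9 to 14 in the neddylation list and from 7 to 22 in the respiratory chain list, and the rising genes from 9 to 15 in the extracellular matrix list.

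In all, 1700 of 12311 genes rose and 2393 fell with hypoxia in DMSO, of which 265 rose and 260 fell at least 2-fold. Without DMSO hypoxia replicate 1 the counts were 1820 and 2948, and 89.4% of the genes called with all libraries kept their call. The share of called genes that rose was 41.5%, and 52.0% under median-of-ratios scaling, with a shift of 0.05 in the median log2 fold change of all genes. A fit of these 6 libraries alone called 944 rising and 1280 falling genes. In the simulated data, false calls for this contrast exceeded the share that the threshold allows.

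**Figure D2:**
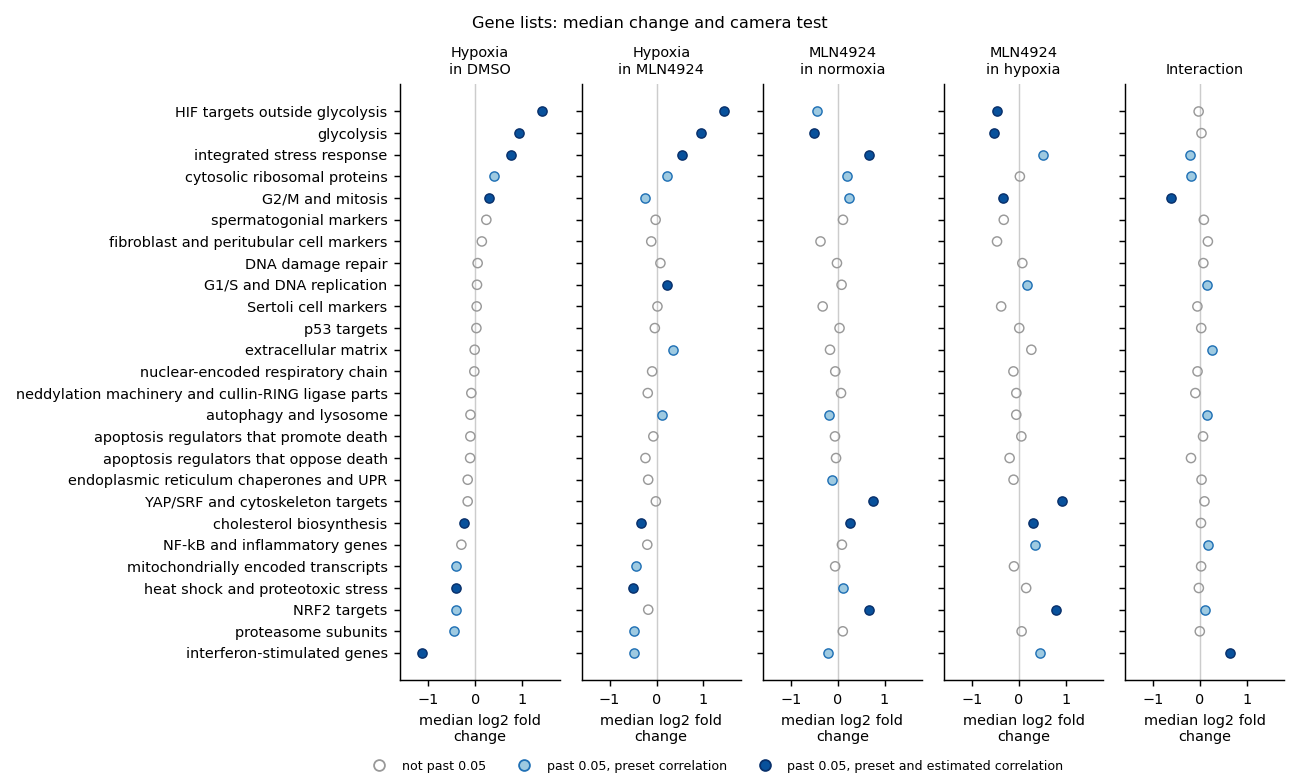
Median log2 fold change over the tested members of each gene list (horizontal axis) for 26 lists (vertical axis) in the 5 contrasts (panels), with open points for lists not past 0.05, light points for lists past 0.05 with the preset correlation and dark points for lists past it with the estimated correlation also. HIF targets lay at 1.42 and 1.43 for hypoxia in DMSO and in MLN4924, and the G2/M list lay at -0.62 and the interferon list at 0.64 in the interaction.

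The effect of the inhibitor at normal oxygen was measured by MLN4924 normoxia against DMSO normoxia. Prl2c2, a proliferin gene of the prolactin family, rose from 20.04 ± 1.56 to 525 ± 16.1 FPKM (log2 fold change 4.65 ± 0.15, adjusted p = 4.22e-08). Its paralog Prl2c3 rose from 1.23 ± 1.00 to 27.2 ± 5.15, although reads of these paralogs are hard to assign. Ccn2, a matricellular YAP target, rose 8.87-fold, from 4.16 ± 0.462 to 44.6 ± 0.917. The smooth muscle genes Tagln and Acta2 rose 7.72-fold and 6.96-fold, Acta2 from 52.5 ± 2.30 to 371 ± 8.38, and Edn1, which encodes endothelin 1, rose 5.67-fold. The transcription factor gene Klf2 fell from 13.6 ± 0.744 to 1.37 ± 0.354 (log2 fold change -2.64 ± 0.14, adjusted p = 1.25e-06). Sprr1a fell from 47.4 ± 0.979 to 11.7 ± 2.06, and Star, the cholesterol carrier of steroid synthesis, fell from 10.7 ± 0.564 to 2.17 ± 1.24. The call of Gnaq (-2.33 ± 0.68, adjusted p = 0.0365) ended with 5 of the libraries left out in turn, with adjusted p up to 0.124.

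Of 33 NRF2 targets, 24 rose and 1 fell with MLN4924 in normoxia (25 and 2 adjusted over the list alone, camera adjusted p = 2.34e-18; adjusted p = 0.0149 with an estimated correlation). NRF2 is itself degraded through a CUL3 ligase. Slc7a11, the cystine transporter, rose from 2.11 ± 0.107 to 13.2 ± 0.197, Nqo1 rose 1.90-fold, from 30.5 ± 1.13 to 58.9 ± 1.19, and Hmox1 rose 1.65-fold. The glutathione transferase genes Gsta1 and Gsta2 rose from 0.207 ± 0.227 to 5.57 ± 0.706 and from 0.190 ± 0.165 to 3.91 ± 0.868, with assignment between them uncertain. In the integrated stress response list 19 of 30 genes rose and 0 fell (23 and 1 adjusted over the list alone, camera adjusted p = 1.28e-16; adjusted p = 0.0145 with an estimated correlation). Chac1 rose 3.27-fold, Asns, the asparagine synthetase, rose 2.23-fold and Trib3 rose 2.10-fold, whereas Ddit3 had a log2 fold change of 0.27 ± 0.12 (adjusted p = 0.172). Of 29 YAP/SRF and cytoskeleton targets 21 rose and 4 fell (22 and 5 adjusted over the list alone, camera adjusted p = 2.28e-12; adjusted p = 0.0145 with an estimated correlation and 0.0509 without DMSO hypoxia replicate 1, which enters through the shared spread). Cholesterol biosynthesis genes rose in 9 of 24 cases and fell in 0 (11 and 0 adjusted over the list alone, camera adjusted p = 4.67e-05; adjusted p = 0.0145 with an estimated correlation; 14 rose without DMSO hypoxia replicate 1), among them Msmo1, which rose 1.76-fold, and Cyp51, which rose 1.49-fold.

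Glycolysis genes fell in 16 of 20 cases and rose in 0, as when adjusted over the list alone (camera adjusted p = 1.86e-09; adjusted p = 0.0113 with an estimated correlation). Ldha, which encodes the A subunit of lactate dehydrogenase, fell from 1093 ± 14.7 to 638 ± 9.93, and Pdk1, which inhibits pyruvate dehydrogenase, fell from 14.2 ± 0.581 to 6.40 ± 0.592. Of 33 HIF targets outside glycolysis 17 fell and 2 rose (18 and 3 adjusted over the list alone, camera adjusted p = 1.14e-05; adjusted p = 0.0694 with an estimated correlation). Bhlhe40 fell from 31.2 ± 1.19 to 10.9 ± 0.758 and Bnip3 from 172 ± 7.77 to 80.9 ± 2.06, while Vegfa did not pass (log2 fold change -0.01 ± 0.07, adjusted p = 0.934) and Hif1a fell by 0.32 on the log2 scale.

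The other lists that passed for MLN4924 in normoxia lost the call with an estimated correlation. Of 40 G2/M genes 14 rose and 0 fell (18 and 0 adjusted over the list alone, camera adjusted p = 6.48e-08; adjusted p = 0.0558 with an estimated correlation, or 0.0872 without DMSO hypoxia replicate 1, where 25 rose), with Incenp, of the chromosomal passenger complex, up 1.53-fold. Of 33 interferon-stimulated genes 11 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 6.76e-04; adjusted p = 0.274 with an estimated correlation). Ribosomal protein genes rose in 4 of 45 cases and fell in 0 (3 and 0 adjusted over the list alone, camera adjusted p = 2.00e-05; adjusted p = 0.627 with an estimated correlation), and 36 rose without DMSO hypoxia replicate 1. Of 29 autophagy and lysosome genes 10 fell and 2 rose (12 and 2 adjusted over the list alone, camera adjusted p = 0.0193; adjusted p = 0.365 with an estimated correlation, or 0.0404 without DMSO hypoxia replicate 1). Atp6v0d1, a subunit of the lysosomal proton pump, fell from 57.7 ± 1.17 to 27.1 ± 2.08. Heat shock genes rose in 8 of 18 cases and fell in 2 (9 and 3 adjusted over the list alone, camera adjusted p = 0.0176; adjusted p = 0.125 with an estimated correlation), with no call under quantile normalization (0.172). In the endoplasmic reticulum and unfolded protein response list 5 of 22 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.0399; adjusted p = 0.525 with an estimated correlation). Leaving out DMSO hypoxia replicate 1 gave 10 falling genes (0.00741, and 0.193 with an estimated correlation). The call with all libraries ended without DMSO normoxia replicate 3 (0.0961), MLN4924 normoxia replicate 1 (0.0595) or MLN4924 normoxia replicate 2 (0.0670).

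Among cell death genes, 3 of 28 that promote death rose and 5 fell with MLN4924 in normoxia (3 and 6 adjusted over the list alone, camera adjusted p = 0.596), and 1 of 16 that oppose it rose and 0 fell (0 and 0 adjusted over the list alone; 0.876). Bmf, a BH3-only gene, fell from 2.04 ± 0.136 to 0.593 ± 0.206, and Htra2, a mitochondrial protease released in apoptosis, rose 1.45-fold. Bbc3 had a log2 fold change of 0.12 ± 0.16 (adjusted p = 0.655). Of 29 p53 targets 6 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.180). Cdkn1a rose 1.87-fold, from 16.9 ± 1.21 to 32.6 ± 1.44, and Plk2 1.88-fold, while Trp53 (0.04 ± 0.07) and Mdm2 (0.07 ± 0.09) were not past the threshold. Neddylation and cullin-RING genes rose in 2 and fell in 1 of 40 cases (2 and 0 adjusted over the list alone, camera adjusted p = 0.241). Nae1 (0.35 ± 0.11, adjusted p = 0.0517) and Cdt1, a replication licensing factor whose protein is a cullin-RING substrate (-0.17 ± 0.06, adjusted p = 0.0520), lay just outside the threshold.

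Lists that did not pass for MLN4924 in normoxia included proteasome subunits (camera adjusted p = 0.0750), NF-kB genes (0.0809), extracellular matrix (0.152), G1/S and DNA replication (0.234), respiratory chain (0.626), mitochondrially encoded transcripts (0.612), DNA damage repair (0.631), spermatogonial markers (0.889), Sertoli cell markers (0.612) and fibroblast markers (0.210). Within the NF-kB list, Ptgs2, which encodes cyclooxygenase 2, rose from 6.53 ± 1.40 to 41.0 ± 7.72. Median, mean and test differed in sign for the death-opposing, DNA damage repair, mitochondrially encoded and spermatogonial lists. The proteasome (0.00259) and fibroblast (0.0404) lists passed without DMSO hypoxia replicate 1, but not with an estimated correlation (0.262 and 0.117). The NF-kB list passed without MLN4924 normoxia replicate 2 (0.0484), but had 0.233 with all libraries and an estimated correlation. In the fit without DMSO hypoxia replicate 1 the rising and falling genes were 4 and 18 for HIF targets, 10 and 4 for heat shock, 3 and 1 for genes that oppose death, and 6 and 3 for the neddylation list.

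MLN4924 in normoxia raised 1149 of 12311 genes and lowered 1318, of which 107 and 98 changed at least 2-fold. Without DMSO hypoxia replicate 1 the counts were 1975 and 2240, and all calls made with it were kept. That library is in neither group and enters only through the shared spread; a fit of the 6 libraries compared called 1928 and 2140. The number that fell was 875 without DMSO normoxia replicate 3.

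The effect of the inhibitor under hypoxia was measured by MLN4924 hypoxia against DMSO hypoxia. Prl2c2 rose from 8.24 ± 2.47 to 192 ± 12.7 FPKM (log2 fold change 4.41 ± 0.15, adjusted p = 3.30e-08). Acta2 rose 14.2-fold, from 27.9 ± 3.802 to 406 ± 15.8, Tagln rose 10.2-fold and Ccn2 rose 7.92-fold. Sprr1a fell from 194 ± 26.9 to 15.3 ± 2.503 (log2 fold change -3.58 ± 0.14, adjusted p = 1.51e-07), Klf2 from 16.9 ± 3.01 to 1.10 ± 0.0929, and the circadian clock genes Dbp and Nr1d1 from 7.46 ± 1.57 to 0.310 ± 0.161 and from 35.2 ± 5.46 to 5.89 ± 1.16. Snord3b1 and Snord3b2, which had identical values in each library and were listed at 0 in both normoxia groups, were lower with MLN4924 (0.630 ± 1.09 against 8.62 ± 8.70), with a spread as large as the mean, and their calls ended without MLN4924 hypoxia replicate 1 (adjusted p = 0.0577) or replicate 3 (0.0603). The rise of Nolc1 was 2.70 ± 0.75 and became 1.52 without DMSO hypoxia replicate 1; its call ended with any 1 of the MLN4924 hypoxia libraries left out (adjusted p 0.0606 to 0.0692).

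Under hypoxia 26 of 33 NRF2 targets rose with MLN4924 and 1 fell (28 and 2 adjusted over the list alone, camera adjusted p = 7.39e-18; adjusted p = 0.0156 with an estimated correlation). Srxn1, a sulfiredoxin, rose from 27.3 ± 1.57 to 110 ± 2.30, Txnrd1, a thioredoxin reductase, rose 3.59-fold and Nqo1 rose 2.86-fold. YAP/SRF targets rose in 19 of 29 cases and fell in 4 (22 and 4 adjusted over the list alone, camera adjusted p = 4.17e-10; adjusted p = 0.0201 with an estimated correlation and 0.0690 without DMSO hypoxia replicate 1). Cholesterol biosynthesis genes rose in 10 of 24 cases and fell in 1 (14 and 2 adjusted over the list alone, camera adjusted p = 3.98e-04; adjusted p = 0.0197 with an estimated correlation). Of 20 glycolysis genes 15 fell and 0 rose (15 and 1 adjusted over the list alone, camera adjusted p = 1.28e-08; adjusted p = 0.0136 with an estimated correlation). Of 33 HIF targets 22 fell and 3 rose (23 and 3 adjusted over the list alone, camera adjusted p = 3.27e-07; adjusted p = 0.0430 with an estimated correlation). Vegfa fell from 139 ± 8.76 to 100.2 ± 4.32 and Bnip3 from 844 ± 229 to 428 ± 28.9, and both values with MLN4924 in hypoxia lay above those in DMSO normoxia, 36.5 ± 1.01 and 172 ± 7.77.

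G2/M and mitosis genes fell in 25 of 40 cases and rose in 1 with MLN4924 in hypoxia (29 and 1 adjusted over the list alone, camera adjusted p = 2.31e-10; adjusted p = 0.0324 with an estimated correlation and 0.0588 without DMSO hypoxia replicate 1). Ccnb2, a mitotic cyclin, fell from 160 ± 23.1 to 91.2 ± 5.27, and Ube2c, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, fell from 180 ± 30.6 to 102 ± 4.27. The lists that follow lost the call with an estimated correlation. Of 46 G1/S and DNA replication genes 15 rose and 0 fell, as when adjusted over the list alone (camera adjusted p = 5.08e-05; adjusted p = 0.0692 with an estimated correlation, or 0.0142 without that library, where 23 rose), among them Ccne1, which encodes cyclin E1, up 1.52-fold. Interferon-stimulated genes rose in 19 of 33 cases and fell in 2 (22 and 2 adjusted over the list alone, camera adjusted p = 3.97e-07; adjusted p = 0.0990 with an estimated correlation). Ifi44 rose from 7.997 ± 0.963 to 27.0 ± 1.05, and Mx2, an antiviral GTPase, from 3.29 ± 0.301 to 6.72 ± 0.777. NF-kB and inflammatory genes rose in 11 of 24 cases and fell in 4 (11 and 5 adjusted over the list alone, camera adjusted p = 0.00619; adjusted p = 0.0692 with an estimated correlation), with Cxcl10 rising from 18.1 ± 3.24 to 60.6 ± 2.87. The integrated stress response list had 20 of 30 genes rising and 2 falling (22 and 3 adjusted over the list alone, camera adjusted p = 1.52e-08; adjusted p = 0.0508 with an estimated correlation), and Atf3, a stress transcription factor, rose 1.92-fold.

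Of genes that promote death, 5 of 28 rose and 5 fell with MLN4924 in hypoxia (6 and 6 adjusted over the list alone, camera adjusted p = 0.834); of those that oppose it, 0 of 16 rose and 3 fell (1 and 4 adjusted over the list alone; 0.210). The survival gene Mcl1 fell from 52.9 ± 8.19 to 41.4 ± 0.520 (adjusted p = 0.0167, and 0.0536 without MLN4924 hypoxia replicate 1), and Bmf fell by 0.93 on the log2 scale. Bbc3 had a log2 fold change of 0.15 ± 0.16 (adjusted p = 0.527). Of 29 p53 targets 8 rose and 4 fell (9 and 5 adjusted over the list alone, camera adjusted p = 0.546), with Plk2 and Eda2r, a receptor of the TNF family, rising 1.94-fold and 2.13-fold. Cdkn1a fell from 161 ± 8.45 to 136 ± 2.16 (adjusted p = 0.0160), a call that ended without MLN4924 hypoxia replicate 2 (0.0531) or replicate 3 (0.0514). Of 40 neddylation and cullin-RING genes 3 rose and 6 fell (3 and 5 adjusted over the list alone, camera adjusted p = 0.771).

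Not past the threshold for MLN4924 in hypoxia were the heat shock (camera adjusted p = 0.0809), respiratory chain (0.135), proteasome (0.151), fibroblast (0.166), unfolded protein response (0.255), DNA damage repair (0.333), autophagy (0.519), Sertoli cell (0.530), ribosomal protein (0.612), mitochondrially encoded (0.612), extracellular matrix (0.729) and spermatogonial (0.771) lists. Median, mean and test differed in sign for the death-promoting and fibroblast lists. The heat shock (0.0411), proteasome (1.88e-07), ribosomal protein (6.49e-09) and fibroblast (0.0130) lists passed without DMSO hypoxia replicate 1. None of them did with an estimated correlation (0.193, 0.0819, 0.117 and 0.0740). The respiratory chain list passed without DMSO hypoxia replicate 2 (0.0151) or replicate 3 (0.00340), but had 0.866 with all libraries and an estimated correlation. In the neddylation list 5 rose and 6 fell without DMSO hypoxia replicate 1.

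In hypoxia, MLN4924 raised 1498 of 12311 genes and lowered 1639, with 157 and 110 changing at least 2-fold. The counts were 2066 and 1927 without DMSO hypoxia replicate 1, where 89.0% of the calls were kept, and 621 and 643 in a fit of the 6 libraries alone. MLN4924 raised 743 genes both in normoxia and in hypoxia, against 139.8 for independent calls, and lowered 813 in both, against 175.5. Calls in both comparisons used the same spread of each gene, so unrelated effects could also share more calls than independent ones. Only 58 genes were called in opposite directions, 34 of them raised in normoxia and lowered in hypoxia. Log2 fold changes of the 2 comparisons, which share no library, had a Pearson r of 0.50 and a Spearman rho of 0.52 across genes, and an r of 0.56 without DMSO hypoxia replicate 1; genes are not independent replicates.

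**Figure D3:**
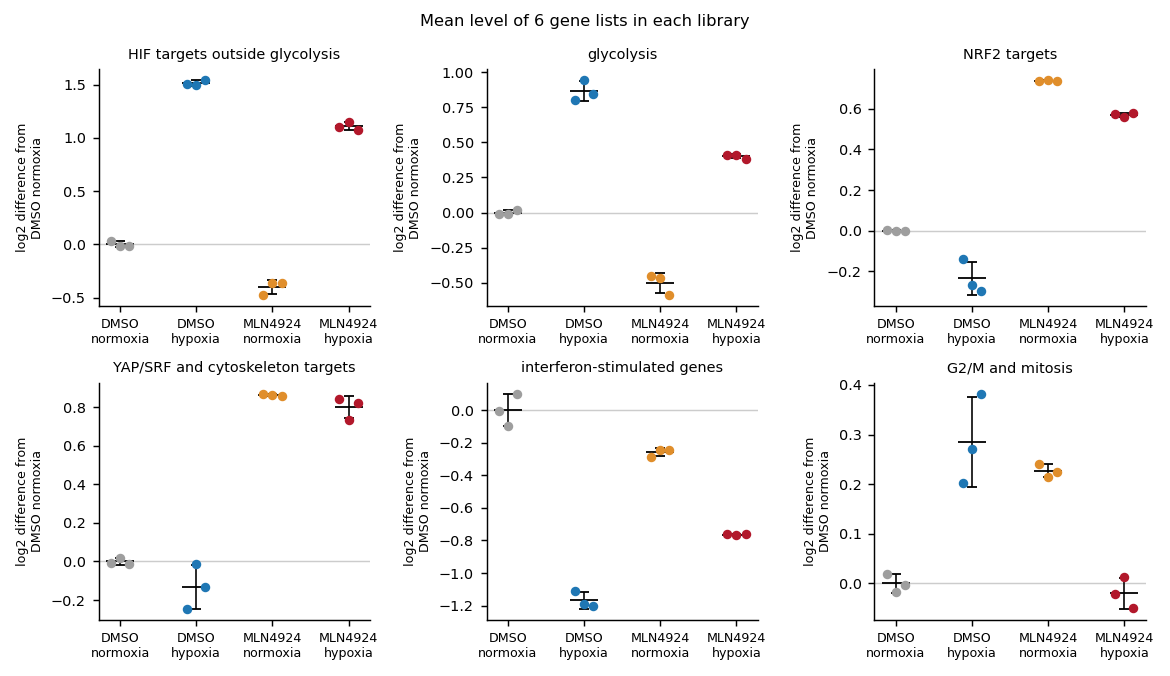
Mean log2 level of 6 gene lists in each library relative to the mean of DMSO normoxia (vertical axis), by group (horizontal axis), with points for libraries and bars for the mean and SD of 3 libraries. HIF targets lay at 1.51 in DMSO hypoxia, 1.11 in MLN4924 hypoxia and -0.40 in MLN4924 normoxia, and NRF2 targets at -0.23, 0.57 and 0.74.

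The response to hypoxia in the presence of the inhibitor was measured by MLN4924 hypoxia against MLN4924 normoxia. Ndrg1 rose from 23.1 ± 1.75 to 306 ± 18.4 FPKM (log2 fold change 3.67 ± 0.08, adjusted p = 4.70e-09). The imprinted noncoding RNA H19 rose from 2.08 ± 0.390 to 31.4 ± 1.96, Ero1a rose 9.93-fold, and Car9, a carbonic anhydrase induced by HIF, rose 8.34-fold, from 19.7 ± 0.666 to 171 ± 3.83. Angptl6 rose from 0.603 ± 0.0702 to 10.5 ± 0.654 and the lipoprotein receptor gene Vldlr from 2.32 ± 0.354 to 25.97 ± 2.20. The chemokines Ccl2 and Ccl7 fell by 2.22 and 1.87 on the log2 scale, Ccl2 from 61.3 ± 2.04 to 12.4 ± 2.00. The immediate early gene Egr1 fell from 20.2 ± 0.215 to 5.46 ± 0.105 and Ifit3 from 50.2 ± 2.40 to 10.9 ± 1.84.

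With MLN4924 present, 28 of 33 HIF targets outside glycolysis rose under hypoxia and 0 fell (30 and 1 adjusted over the list alone, camera adjusted p = 2.27e-27; adjusted p = 0.00317 with an estimated correlation). Bnip3 rose 5.24-fold, from 80.9 ± 2.06 to 428 ± 28.9, and Vegfa rose 2.72-fold. Glycolysis genes rose in 19 of 20 cases and fell in 0, also when adjusted over the list alone (camera adjusted p = 5.28e-18; adjusted p = 0.00317 with an estimated correlation), and Slc2a1, the glucose transporter GLUT1, rose from 58.8 ± 1.00 to 202 ± 5.09. The integrated stress response list had 24 of 30 rising and 0 falling (25 and 0 adjusted over the list alone, camera adjusted p = 1.88e-15; adjusted p = 0.0149 with an estimated correlation), with Ddit3 rising 3.59-fold, from 31.1 ± 5.07 to 113 ± 6.12. G1/S and DNA replication genes rose in 19 of 46 cases and fell in 1 (20 and 2 adjusted over the list alone, camera adjusted p = 3.97e-07; adjusted p = 0.0324 with an estimated correlation). E2f1, a transcription factor of S phase entry, rose 1.75-fold and Cdt1 rose from 38.2 ± 0.571 to 53.2 ± 1.86. Heat shock genes fell in 13 of 18 cases and rose in 1 (14 and 1 adjusted over the list alone, camera adjusted p = 2.45e-07; adjusted p = 0.0143 with an estimated correlation). Cholesterol biosynthesis genes fell in 11 of 24 and rose in 2 (16 and 2 adjusted over the list alone, camera adjusted p = 0.00300; adjusted p = 0.0355 with an estimated correlation).

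Other lists that passed for hypoxia in MLN4924 lost the call with an estimated correlation. Of 33 interferon-stimulated genes 18 fell and 2 rose (22 and 4 adjusted over the list alone, camera adjusted p = 8.29e-06; adjusted p = 0.139 with an estimated correlation). Of 32 proteasome subunits 23 fell and 1 rose (25 and 1 adjusted over the list alone, camera adjusted p = 3.44e-09; adjusted p = 0.319 with an estimated correlation, or 0.0396 without DMSO hypoxia replicate 1). Psmd1 fell from 112 ± 1.87 to 57.3 ± 1.64. G2/M genes fell in 13 of 40 cases and rose in 0 (14 and 1 adjusted over the list alone, camera adjusted p = 1.74e-04; adjusted p = 0.174 with an estimated correlation), with Cdc20 falling from 128 ± 1.17 to 67.9 ± 5.76 and Plk1 from 103 ± 4.52 to 58.6 ± 3.62. Of 29 extracellular matrix genes 11 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 3.26e-04; adjusted p = 0.525 with an estimated correlation, or 0.0124 without DMSO hypoxia replicate 1), and Lox, the collagen crosslinking enzyme, rose 2.21-fold. Ribosomal protein genes rose in 6 of 45 cases and fell in 0 (5 and 0 adjusted over the list alone, camera adjusted p = 1.54e-05; adjusted p = 0.625 with an estimated correlation), and 33 rose without that library. Mitochondrially encoded transcripts fell in 6 of 13 cases and rose in 0 (7 and 0 adjusted over the list alone, camera adjusted p = 0.00221; adjusted p = 0.319 with an estimated correlation). Autophagy and lysosome genes rose in 10 of 29 cases and fell in 2 (10 and 3 adjusted over the list alone, camera adjusted p = 0.0338; adjusted p = 0.403 with an estimated correlation). The call ended without MLN4924 hypoxia replicate 3 (0.0622) or MLN4924 normoxia replicate 3 (0.0662). In the fit without DMSO hypoxia replicate 1 the rising and falling genes were 14 and 5 for this list, 5 and 22 for interferon-stimulated genes, 28 and 4 for G1/S and DNA replication, and 2 and 17 for cholesterol biosynthesis.

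Of genes that promote death, 6 of 28 rose and 6 fell with hypoxia in MLN4924 (6 and 7 adjusted over the list alone, camera adjusted p = 0.596). Of those that oppose it 0 of 16 rose and 3 fell (0 and 2 adjusted over the list alone; 0.115), and 6 fell without DMSO hypoxia replicate 1. Bbc3 rose from 1.97 ± 0.370 to 5.36 ± 0.844 and Mcl1 fell from 62.3 ± 0.888 to 41.4 ± 0.520 (log2 fold change -0.58 ± 0.09, adjusted p = 7.28e-04). Of 29 p53 targets 8 rose and 7 fell (9 and 8 adjusted over the list alone, camera adjusted p = 0.484), with Cdkn1a rising 4.07-fold, from 32.6 ± 1.44 to 136 ± 2.16, and Trp53 falling from 2150 ± 23.2 to 1534 ± 89.9. Of 40 neddylation and cullin-RING genes 1 rose and 10 fell, also when adjusted over the list alone (camera adjusted p = 0.0669, and 0.0237, 0.0412 and 0.0455 without DMSO hypoxia replicate 1, MLN4924 hypoxia replicate 2 and MLN4924 normoxia replicate 2). The first of these became 0.117 with an estimated correlation, with 3 rising and 17 falling genes, and with all libraries the list had 0.349. NRF2 targets (5 rising and 12 falling, camera adjusted p = 0.115), NF-kB genes (0.183), DNA damage repair (0.103), the respiratory chain (0.317), the unfolded protein response (0.545), YAP/SRF targets (0.876) and the spermatogonial (0.519), Sertoli cell (0.484) and fibroblast (0.426) markers did not pass. Median, mean and test differed in sign for the p53, death-promoting, YAP/SRF, spermatogonial and fibroblast lists.

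Hypoxia in MLN4924 raised 1439 of 12311 genes and lowered 2034, with 208 and 112 changing at least 2-fold. The counts were 2199 and 3043 without DMSO hypoxia replicate 1, which again enters only through the shared spread, and all calls were kept. The share of called genes that rose was 41.4%, and 50.3% under median-of-ratios scaling. Hypoxia raised 944 genes with either treatment, against 198.7 for independent calls, and lowered 1369 with either, against 395.4, while 38 were called in opposite directions. These calls too used the same spread of each gene and were not independent. Across genes the Pearson r of the 2 hypoxia effects, which share no library, was 0.60 and the Spearman rho 0.62, and r was 0.65 without DMSO hypoxia replicate 1.

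Whether the inhibitor altered the response to hypoxia was measured by the interaction, where a positive value means a larger rise or a smaller fall under hypoxia with MLN4924 than with DMSO. Cdc20, the activator of the anaphase-promoting complex, stood at 100.1 ± 2.53 FPKM in DMSO normoxia and 105 ± 3.46 in DMSO hypoxia, but at 128 ± 1.17 and 67.9 ± 5.76 with MLN4924, an interaction of -0.97 ± 0.08 on the log2 scale (adjusted p = 0.00143). Ifi44 fell under hypoxia with DMSO, from 22.1 ± 4.60 to 7.997 ± 0.963, and stood at 19.0 ± 2.26 and 27.0 ± 1.05 with MLN4924 (interaction 1.84 ± 0.20, adjusted p = 0.00198). Nr1d1, which encodes the clock repressor REV-ERBα, went from 20.7 ± 0.261 to 35.2 ± 5.46 with DMSO and from 13.6 ± 0.588 to 5.89 ± 1.16 with MLN4924 (-1.82 ± 0.18, adjusted p = 0.00178). Sprr1a, which encodes a cornified envelope protein, went from 47.4 ± 0.979 to 194 ± 26.9 with DMSO and from 11.7 ± 2.06 to 15.3 ± 2.503 with MLN4924 (-1.64 ± 0.20). Cdkn1a, up 9.04-fold under hypoxia with DMSO and 4.07-fold with MLN4924, had an interaction of -1.15 ± 0.09 (adjusted p = 8.52e-04). Trib3 (-1.42 ± 0.13), Slc7a11 (-1.22 ± 0.16) and Adm (-1.34 ± 0.18) also rose less with MLN4924 or, for Slc7a11, went from 13.2 ± 0.197 to 11.3 ± 0.767.

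**Figure D4:**
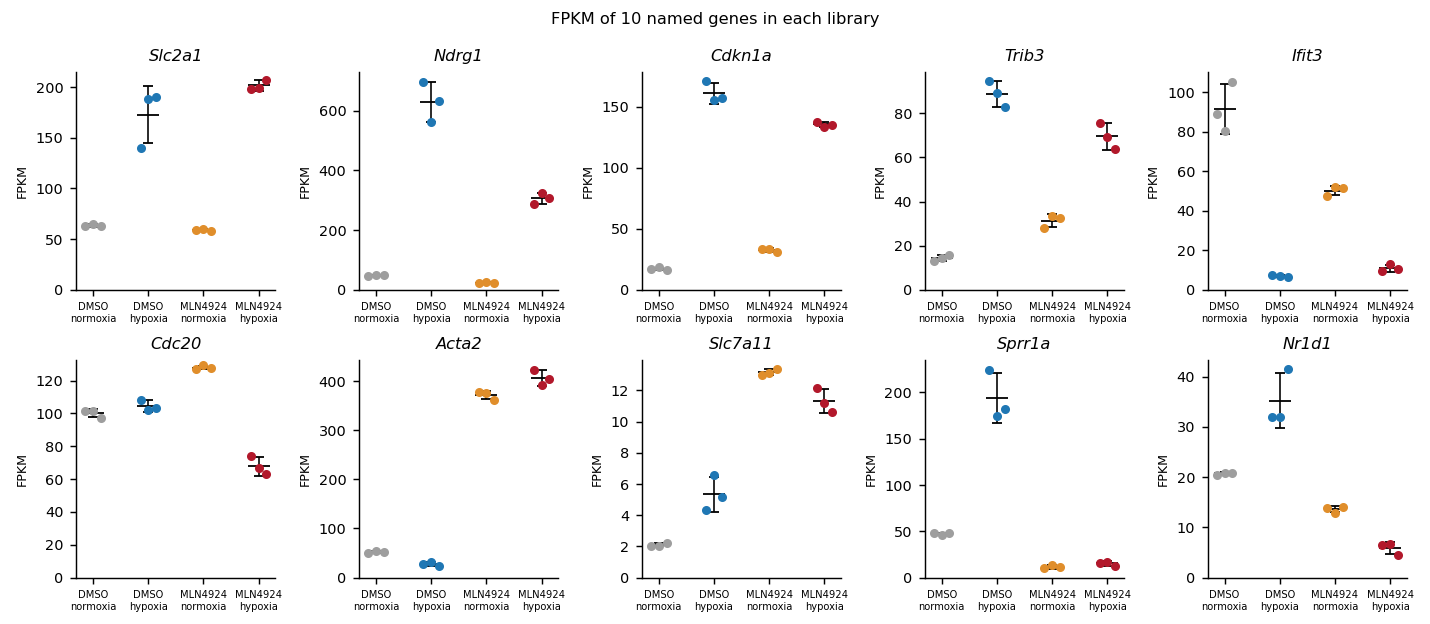
FPKM (vertical axes, from 0) of 10 named genes in each library by group, with points for libraries and bars for the mean and SD of 3 libraries. Cdc20 stood at 67.9 ± 5.76 in MLN4924 hypoxia against 100.1 ± 2.53 to 128 ± 1.17 in the other groups, and Cdkn1a at 161 ± 8.45 in DMSO hypoxia and 136 ± 2.16 in MLN4924 hypoxia.

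In the G2/M and mitosis list 20 of 40 genes had a negative interaction past the threshold and 0 a positive one (35 and 0 adjusted over the list alone, camera adjusted p = 2.81e-34; adjusted p = 0.00317 with an estimated correlation). The list mean lay 0.28 ± 0.09 (SD) above DMSO normoxia in DMSO hypoxia and 0.23 ± 0.01 above it in MLN4924 normoxia, but at -0.02 ± 0.03 in MLN4924 hypoxia. Outside this list, the spindle protein gene Ckap2, a member of the p53 list, went from 26.1 ± 2.39 to 33.6 ± 2.78 with DMSO. With MLN4924 it went from 36.8 ± 0.626 to 25.4 ± 1.20 (interaction -0.87 ± 0.11). The calls of Cenpa (-1.02 ± 0.22) and Cks2 (-0.995 ± 0.20) held with DMSO hypoxia replicate 1 left out, which moved them to -0.79 each, but ended with 9 and 10 of the 12 libraries left out in turn (adjusted p up to 0.126 and 0.0966). In the interferon-stimulated list 12 of 33 genes had a positive interaction and 0 a negative one (22 and 0 adjusted over the list alone, camera adjusted p = 9.63e-21; adjusted p = 0.0145 with an estimated correlation, or 0.0231 without DMSO hypoxia replicate 1, where 21 were positive and 0 negative). Ifit3 fell from 91.6 ± 12.7 to 6.98 ± 0.571 with DMSO and from 50.2 ± 2.40 to 10.9 ± 1.84 with MLN4924 (1.41 ± 0.17). Cxcl10, which is in the NF-kB list and not in this one, had an interaction of 1.06 ± 0.15.

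Other lists passed in the interaction with the preset correlation only. The integrated stress response list had 7 of 30 negative and 0 positive (9 and 2 adjusted over the list alone, camera adjusted p = 3.58e-06; adjusted p = 0.0993 with an estimated correlation), with Chac1 at -1.01 ± 0.11 and Asns at -0.90 ± 0.10. The list mean was nevertheless highest with both treatments. It lay 0.86 ± 0.05 (SD) above DMSO normoxia in DMSO hypoxia, 0.61 ± 0.05 in MLN4924 normoxia and 1.29 ± 0.02 in MLN4924 hypoxia. G1/S and DNA replication genes were positive in 4 of 46 and negative in 0 (10 and 1 adjusted over the list alone, camera adjusted p = 8.77e-04; adjusted p = 0.125 with an estimated correlation, or 0.0210 without DMSO hypoxia replicate 1, where 9 were positive and 0 negative). NRF2 targets were positive in 4 of 33 and negative in 2 (8 and 3 adjusted over the list alone, camera adjusted p = 0.00843; adjusted p = 0.389 with an estimated correlation, or 0.0124 without DMSO hypoxia replicate 1, where 13 were positive and 2 negative). Srxn1 lay at 0.55 ± 0.07. The list did not pass without DMSO hypoxia replicate 2 (0.0545) or replicate 3 (0.0682). Extracellular matrix genes were positive in 2 of 29 and negative in 1 (5 and 1 adjusted over the list alone, camera adjusted p = 5.57e-04; adjusted p = 0.542 with an estimated correlation). The list level of DMSO hypoxia replicate 1 was -0.29 against 0.26 and 0.23 in its group, and without that library the list median of 0.26 became 0.09, with 8 positive and 4 negative (0.00760, and 0.0509 with an estimated correlation). NF-kB genes were positive in 1 of 24 and negative in 0 (5 and 0 adjusted over the list alone, camera adjusted p = 0.0259; adjusted p = 0.125 with an estimated correlation, or 0.0690 without DMSO hypoxia replicate 1, where 5 were positive and 0 negative). The call ended without DMSO hypoxia replicate 3 (0.0636) or MLN4924 hypoxia replicate 2 (0.0540). Autophagy genes were positive in 1 of 29 and negative in 0, also when adjusted over the list alone (camera adjusted p = 0.0226; adjusted p = 0.378 with an estimated correlation, or 0.0184 without DMSO hypoxia replicate 1, where 6 were positive and 0 negative). The preset call ended without DMSO hypoxia replicate 2 (0.101) or replicate 3 (0.12). Ribosomal protein genes had no member past the threshold, with 0 positive and 0 negative of 45 also when adjusted over the list alone (camera adjusted p = 9.56e-05; adjusted p = 0.663 with an estimated correlation). The list call ended without DMSO hypoxia replicate 1 (0.284).

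No list of cell death genes passed by camera in the interaction. Of 28 genes that promote death 0 had an interaction past the threshold, also adjusted over the list alone (camera adjusted p = 0.320); the member with the smallest p, Casp9, the initiator caspase of the mitochondrial pathway, had 0.46 ± 0.14 (adjusted p = 0.155). Of 16 genes that oppose death 0 passed (0 positive and 2 negative adjusted over the list alone, camera adjusted p = 0.0779, but 0.0116 without DMSO hypoxia replicate 1 and 0.0484 without MLN4924 normoxia replicate 2). With an estimated correlation the former was 0.0678, and the list had 0.182 with all libraries. By fry, which does not compare a list with other genes, the death-opposing list passed in the interaction (adjusted p = 0.00259, list median -0.19), for hypoxia in MLN4924 (6.31e-06, -0.24), for MLN4924 in hypoxia (4.94e-04, -0.20) and for hypoxia in DMSO (0.00584, -0.11). The death-promoting list did not pass by fry in any contrast (0.0610 to 0.740), and the p53 list passed in the pairwise contrasts (8.75e-04 to 0.00695) but not in the interaction (0.641). The p53 list medians were small, at 0.02 for hypoxia in DMSO and -0.04 for hypoxia in MLN4924. They were 0.04 for MLN4924 in normoxia and 0.01 for MLN4924 in hypoxia. Members were called in both directions except for MLN4924 in normoxia. Birc5 had -0.76 ± 0.18 (adjusted p = 0.0695, but 0.00179 without DMSO hypoxia replicate 1). Bbc3 (0.02 ± 0.22), Ddit3 (0.09 ± 0.18), Bnip3 (0.13 ± 0.20) and Mdm2 (-0.27 ± 0.13) did not pass. Of 29 p53 targets 1 was positive and 2 were negative (2 and 3 adjusted over the list alone, camera adjusted p = 0.876), the negative ones being Cdkn1a and Ckap2, and the positive one Eda2r (0.75 ± 0.15), whose call ended with 10 of the 12 libraries left out in turn (adjusted p 0.0563 to 0.0885).

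The HIF targets had 2 positive and 1 negative of 33 (5 and 4 adjusted over the list alone, camera adjusted p = 0.472) and the glycolysis genes 0 of 20 (0.768), so the interaction test gave no call for either list as a set. The counts were 6 and 4, and 3 and 0, without DMSO hypoxia replicate 1. Also not past were the heat shock (camera adjusted p = 0.876), unfolded protein response (0.427), DNA damage repair (0.524), neddylation (0.0715), proteasome (0.781), cholesterol (0.896), respiratory chain (0.233), mitochondrially encoded (0.885), YAP/SRF (0.434), spermatogonial (0.980), Sertoli cell (0.876) and fibroblast (0.545) lists. Median, mean and test differed in sign for the glycolysis, p53, heat shock, proteasome, cholesterol, mitochondrially encoded and spermatogonial lists. The unfolded protein response list passed without DMSO hypoxia replicate 1 (0.0136), as did the proteasome (1.94e-04) and respiratory chain (0.00739) lists, in the direction opposite to that with all libraries. None of the 3 passed with an estimated correlation (0.221, 0.186 and 0.257). The respiratory chain list passed in its original direction without DMSO hypoxia replicate 2 (0.0253) or replicate 3 (0.00525), but had 0.894 with all libraries and an estimated correlation. Without DMSO hypoxia replicate 2, MLN4924 hypoxia replicate 2, DMSO normoxia replicate 3 or MLN4924 normoxia replicate 2 the neddylation list passed, with adjusted p from 0.0386 to 0.0479. With all libraries and an estimated correlation it had 0.349.

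In the interaction 118 genes were positive and 114 negative of 12311, with 33 and 23 of them at or beyond 2-fold. There were 406 and 272 without DMSO hypoxia replicate 1, and 99.6% of the calls were kept. Leaving out any 1 of the MLN4924 or DMSO normoxia libraries gave 42 to 58 positive and 48 to 73 negative genes. Of 41 named genes called, 19 kept their call with each library left out in turn, among them Cdc20, Cdkn1a, Ifi44, Ifit3, Nr1d1, Sprr1a, Trib3, Acta2 and Slc7a11.

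**Figure D5:**
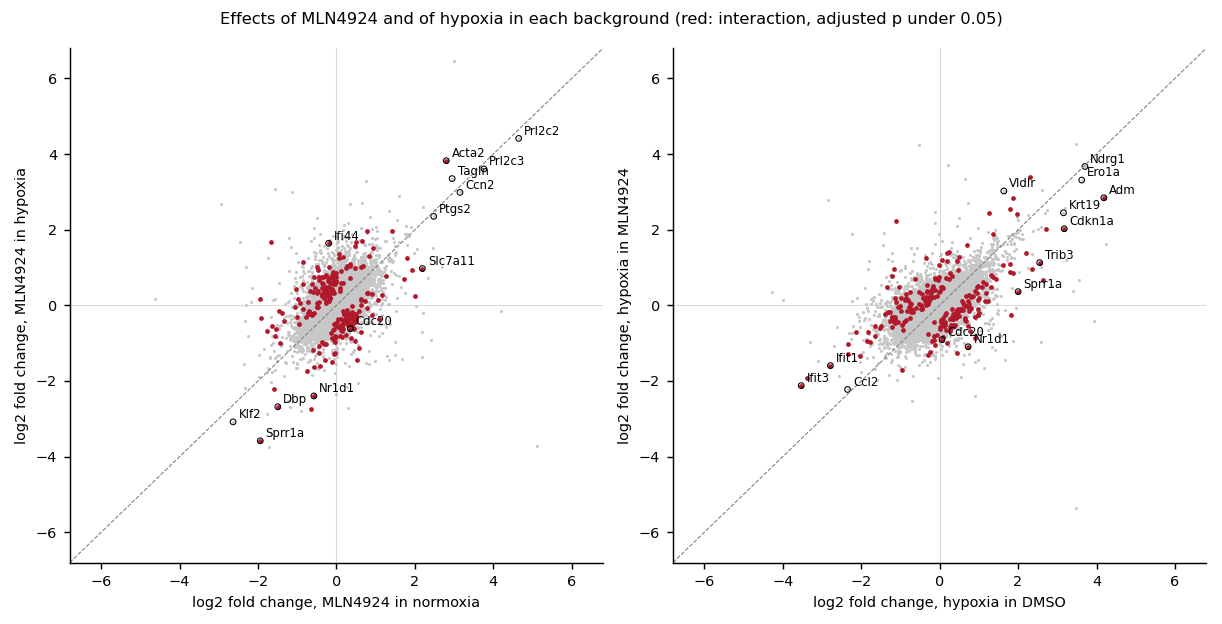
Log2 fold changes of all tested genes (points), with MLN4924 in hypoxia against MLN4924 in normoxia (left panel, vertical against horizontal axis) and hypoxia in MLN4924 against hypoxia in DMSO (right panel), the dashed line marking equal effects and red the genes past the threshold in the interaction. Acta2 lay at 2.80 and 3.82 in the left panel, and Cdkn1a at 3.18 (DMSO) and 2.03 (MLN4924) in the right panel.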

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

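The lists, the interaction test, the scalings and the leaving out of each library were chosen before the data were examined, and removal of the length trend after. The use of these values to weigh explanations of the G2/M and interferon results, and the bounds that decide them, were chosen after seeing those results, whereas the bound for the regroupings of libraries was set before. The analysis looked for effects of hypoxia that differed between MLN4924 and DMSO. There were 118 genes with a larger rise or smaller fall with MLN4924 and 114 with the opposite. Of 100 regroupings of the 12 libraries, the real one included, 1 called as many as 232 genes and the highest other called 2, so chance assignment of libraries was excluded.

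G2/M and mitosis genes had a camera adjusted p of 2.81e-34 in the interaction. DMSO hypoxia replicate 1 was excluded as the cause, because the median interaction over 40 members was -0.62 ± 0.05 without it (adjusted p = 0.0124 with an estimated correlation). A transcript length trend was excluded, with a median of -0.64 ± 0.03 once it was removed. The errors of both medians take members as independent and leave out the spread between libraries. A shift of cells from G2/M towards S phase could not be settled, because the 46 genes of the G1/S and DNA replication list had an adjusted p of 0.125 with an estimated correlation (0.0210 without DMSO hypoxia replicate 1) and 8.77e-04 with the preset correlation. Cell cycle phase was not measured, and DNA content by flow cytometry in the 4 groups would separate a change of phase from a change of transcription.

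Interferon-stimulated genes had a camera adjusted p of 9.63e-21 in the interaction. Without DMSO hypoxia replicate 1 the median over 33 members was 0.64 ± 0.10 (adjusted p = 0.0231 with an estimated correlation), which excluded that library as the cause. Compression of low values by the added 1 FPKM was excluded as the whole cause, because it cannot turn a lower level into a higher one. With MLN4924 in hypoxia 19 of 33 members rose and 2 fell, with a median of 0.46 ± 0.09 and a fry adjusted p of 4.20e-05. Against other genes the list did not pass there with an estimated correlation (0.0990, or 0.147 without DMSO hypoxia replicate 1), and the error of the median takes members as independent. A part played by compression stays open. Library scaling was excluded, with a median of 0.62 ± 0.10 under median-of-ratios scaling, the setting nearest to 0.

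The other lists past the threshold were the integrated stress response (3.58e-06), ribosomal proteins (9.56e-05), extracellular matrix (5.57e-04), G1/S and DNA replication (8.77e-04), NRF2 targets (0.00843), autophagy and lysosome (0.0226) and NF-kB genes (0.0259). With an estimated correlation none of these passed over all 12 libraries. Without DMSO hypoxia replicate 1, G1/S and DNA replication (0.0210), NRF2 targets (0.0124) and autophagy and lysosome (0.0184) passed with it, and the ribosomal protein call with the preset correlation ended (0.284).

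Among genes with a positive difference on the log2 scale were Star (2.13), Ifi44 (1.84), Rgcc (1.58), Xdh (1.52), Ifit3b (1.46), Iigp1 (1.42), Ifit3 (1.41), Cxcl10 (1.06), Acta2 (1.02), Eda2r (0.75), Nqo1 (0.59), Srxn1 (0.55), P4ha2 (0.52), Mcm2 (0.49), Bhlhe40 (0.43), Lig1 (0.38), Mmp2 (0.38), Cdt1 (0.37), Bgn (0.37), Sqstm1 (0.36) and Hspb8 (0.28). Those with a negative difference were AY036118 (-1.96), Nr1d1 (-1.82), Lce1g (-1.75), Sprr1a (-1.64), Trib3 (-1.42), Smtnl2 (-1.37), Adm (-1.34), Slc7a11 (-1.22), Cdkn1a (-1.15), Cenpa (-1.02), Chac1 (-1.01), Cks2 (-0.995), Cdc20 (-0.97), Asns (-0.90), Ckap2 (-0.87), Egr1 (-0.76), Junb (-0.71), H2ax (-0.55) and Rad21 (-0.40). Of the 41 named genes called in the interaction, 22 lost the call with at least 1 library left out. The number of the 12 libraries that ended a call ran from 1 for Ifit3b to 10 for Eda2r, Nqo1, H2ax, Cks2, Cdt1 and Hspb8. It was 8 for Star and 9 for AY036118, which had the largest differences in each direction, and 9 for Xdh.

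For the pairwise comparisons the 10 splits of 6 libraries are too few for a share under 0.05, so chance cannot be told apart from an effect by this test alone. In each, 1 split, the real one, called as many genes: 4093 for hypoxia in DMSO (highest other 6), 2467 for MLN4924 in normoxia (highest other 1), 3137 for MLN4924 in hypoxia (highest other 1) and 3473 for hypoxia in MLN4924 (highest other 2). A real effect adds to the scatter within groups in the other splits, which lowers their counts.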

How the results depend on the processing

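Several alternatives moved counts of calls by over 1.5 times, and no cause was tested beyond leaving out single libraries. DMSO hypoxia replicate 1 enters the contrast of MLN4924 in normoxia only through the shared spread. Without it 1975 genes rose and 2240 fell there, against 1149 and 1318 with all libraries. In fits of only the groups compared, 944 genes rose and 1280 fell with hypoxia in DMSO, 1928 and 2140 with MLN4924 in normoxia, and 621 and 643 with MLN4924 in hypoxia, with 937 shared MLN4924 calls. With array weights 2098 rose and 2426 fell with MLN4924 in normoxia, 2236 and 3103 with hypoxia in MLN4924, and 478 and 365 in the interaction, with 2667 shared MLN4924 and 3627 shared hypoxia calls. Removing the length trend gave 209 and 209 in the interaction.

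A replicate block left 56 positive interaction genes. Of 18 pairs of libraries with the same number 0 had residuals correlated above 0.1 (r -0.070 to 0.099). The median r was 0.010 for these pairs and -0.0087 for pairs with different numbers. Any pairing was weak, but a bound on r cannot show that the numbers do not pair.

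With each library left out in turn, MLN4924 in normoxia gave 773 to 1975 rising and 875 to 2240 falling genes, hypoxia in MLN4924 1062 to 2199 rising, the interaction 42 to 406 positive and 48 to 272 negative, and shared MLN4924 calls 1158 to 2580. The highest of each was without DMSO hypoxia replicate 1.

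Of 384 calls of named genes 279 held in every alternative, and of 55 list calls 26 did. mt-Atp8 for hypoxia in MLN4924 moved from a fall to 1.78e-15 under quantile normalization. Direction also changed for lists not past the threshold. Fibroblast markers did so for MLN4924 in hypoxia (fry 0.00251). Proteasome subunits did so in the interaction (quantile 0.0281, array weights 0.00122, and 1.94e-04 without DMSO hypoxia replicate 1). So did the respiratory chain in the interaction (array weights 0.0325, and 0.00739 without DMSO hypoxia replicate 1). With single libraries left out, in either direction, the adjusted p of proteasome subunits ran from 1.94e-04 to 0.896. That of the respiratory chain ran from 0.00525 to 0.338. No scaling moved the median log2 fold change of all genes by over 0.1.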

Other observations

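Of the tests in this part, the scalings were chosen before the data were examined and removal of the length trend after. The bounds by which both decide were set after seeing the result, and the bound for damping before it. The title of the series concerns apoptosis, and some of the largest effects of MLN4924 lay elsewhere. Prl2c2 rose from 20.04 ± 1.56 to 525 ± 16.1 FPKM in normoxia, and the contractile genes Acta2 and Tagln and the YAP target Ccn2 rose at least 6.96-fold. The clock gene Nr1d1 fell from 35.2 ± 5.46 to 5.89 ± 1.16 with MLN4924 in hypoxia.

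Most markers of germ cells that were in the file were low. Of 22 spermatogonial markers 12 were in the file and 4 had a mean of at least 1 FPKM over the 12 libraries, the highest being Ccnd2 at 30.9, and of 23 spermatocyte and spermatid markers 8 were in the file and 1 did, Crem at 6.05. Of the 24770 symbols in the file, 0 were listed at 0 in all 12 libraries, so the file has no rows for genes undetected throughout. Whether a marker absent from the file was undetected or listed under another name was not tested. Absent markers are therefore left out of these counts. Of the 14 fibroblast and peritubular markers in the file 9 did, with S100a4 at 1491 and Vim at 828, and of the 13 Sertoli cell markers in the file 9 did, with Ctsl at 88.8. The Leydig list had 2 of 5 in the file, with Nr5a1 at 23.0, and the macrophage list 2 of 6, with Cd14 at 9.61. Many of these markers are not specific to 1 cell type, and no reference cell line was compared.

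With MLN4924 in normoxia 16 of 20 glycolysis genes fell and 0 rose (adjusted p = 0.0113 with an estimated correlation). Of 33 HIF targets outside glycolysis 17 fell, 2 rose and 14 did not pass, and the list lost its call with an estimated correlation (0.0694, or 0.0740 without DMSO hypoxia replicate 1). A damping of each gene in proportion to its response to hypoxia cannot be told apart from other causes, because the Spearman correlation across 53 members was -0.181 (permutation p = 0.186). A transcript length trend was excluded, with a median of -0.46 ± 0.03 over 52 members once it was removed. Library scaling was excluded, with a median of -0.46 ± 0.03 under median-of-ratios scaling, the setting nearest to 0. The errors of both medians take members as independent and leave out the spread between libraries. HIF1A protein was not measured, and its level with and without MLN4924 in normoxia would test whether less HIF activity explains the fall.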
